A study of Caenorhabditis elegans with 4 samples.

How the data were processed

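The series comprised 4 libraries from adult fem-2(b245) Caenorhabditis elegans, 2 of COH-3 ChIP DNA and 2 of input DNA. Per the labels' protocols, the animals were harvested as gravid adults, while the stage label reads young adult with a germ line. Frozen, ground worms were crosslinked for 20 min with EGS, a protein crosslinker, and for 10 min with EGS and formaldehyde, and the chromatin was sheared by sonication. Recovered DNA was made into single-end Illumina libraries. Whole animals were used, so peaks are not assigned to a tissue.

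Reads were aligned with BWA to ce10, per the submitters' processing notes, which give no version. The deposited files are peak lists in GFF3, a table format for genome features, and their coordinates are on WormBase WS220, per the file headers. Per the source column of the files, the list of each replicate was called with MACS and the series-wide list with MACS v2. Each peak has a score, deposited by the authors on the caller's own scale, which the files do not name. Replicate scores started at 50.02 and 50.04 and were tied at 3100 in 31 and 118 peaks, while those of the series-wide list ran from 1.38 to 186.41, so scores were used only to rank peaks within their own list. The caller's threshold, its use of the input libraries, duplicate removal and the way the series-wide list combines the libraries are not given in the sources used here. The replicate lists and the series-wide list thus name different callers and may follow different thresholds, which could change their number and width of peaks. Read depth is unknown, so no coverage or enrichment was computed, and a longer list can reflect deeper sequencing as well as more binding. No column of another sample was present (0 columns).

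From these lists, peak numbers, widths and covered bases were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. Comparisons used the 6 nuclear chromosomes, leaving out 1 mitochondrial peak of replicate 1 and 3 of the series-wide list. The extent of each chromosome was taken from base 1 to the largest peak end in any list, 100.27 Mb in all, because no table of WS220 chromosome lengths was at hand to check them against. The extents are therefore approximate, and may run slightly past the true chromosome ends where the caller extended a terminal peak. Overlap between lists required 1 bp. It was compared with 100000 shifts of one list, each moving all peaks of a chromosome around it by one random distance, which keeps widths and spacing (one-sided permutation test, seed 1). Densities on X, on each chromosome and in the central 33.3% of the length of the autosomes were compared with the share of length by two-sided exact binomial tests in each replicate, with Benjamini-Hochberg adjustment over the replicates or over the 12 chromosome tests. A difference was called when both replicates passed 0.05 in the same direction. Where an alternative rests on a single list, it was called when that list passed. Differences between replicates were tested with two-sided Fisher's exact tests on peak numbers, added after the data were examined, as was the recurrence of X and autosomal peaks. Intervals are 95% Clopper-Pearson intervals. These tests treat peaks as independent, which they are not, so the agreement of the 2 libraries is the only replicate check. With 2 ChIP libraries, no test across libraries was made.

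The tests were tested on simulated data. Of 60 simulated pairs of independent lists with the sizes and widths of the replicates, 7 gave p under 0.05 in the overlap test with 200 shifts each, against 3 expected, and all 60 pairs with a planted overlap of 30% did. A planted log2 density of -1 on X was recovered as -0.98 ± 0.12 (SD over 60 lists of 1812 peaks). Of 60 lists of 3332 peaks without a planted difference, 1 gave p under 0.05. Simulated peaks were placed independently, as the binomial test assumes. The simulations therefore do not show how closely spaced real peaks affect that test.

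The rule for the sites described was set before the data were examined: without a usable annotation, the 10 highest-scoring series-wide peaks that overlap both replicates, by coordinates. The planned comparisons with gene starts, feature classes, gene lists and GC content were not made, because the gene table used here is on WBcel235 and no sequence or annotation of WS220 was at hand. The alternatives tried were a stricter score threshold (the better-scoring 50% of each list), equal numbers of peaks (1812) from both replicates, merging of peaks closer than 500 bp, overlap of 50% of the peak or of midpoints within 500 bp, shifts of 10 to 100 kb, covered bases in place of peak numbers, the central 50% of the length, X left out, the series-wide list, regions marked in both replicates, and each replicate alone. Leaving out peaks within 1 kb of a chromosome end or wider than 5 kb, and setting each autosome against the other autosomes (10 tests), were added after the data were examined.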

Results

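COH-3 binding was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in adult Caenorhabditis elegans. COH-3 is a kleisin, the ring-closing subunit of a meiotic form of cohesin, the complex that holds sister chromatids together. The animals were fem-2(b245) hermaphrodites with a germ line, kept at 20 °C. The gene fem-2 is a sex determination gene whose loss feminizes the germ line. Whether the germ line of these animals was feminized at that temperature was not assessed here. The study held 4 libraries, of which 2 were ChIP libraries made with a rabbit antibody to COH-3 and 2 were input DNA libraries. The labels number the ChIP libraries 1 and 2 without stating whether they came from separate cultures, so differences between them may be technical. Values were available as peak lists of the 2 ChIP libraries and another list for the whole series. The input libraries were not analysed here, and no value below is a ratio to input made from their reads. The read depth of the libraries is unknown.

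The 2 ChIP libraries yielded lists of different size. Replicate 1 had 1813 peaks and replicate 2 had 3332, a mean of 2573 ± 1074 (SD, n = 2). On the 6 nuclear chromosomes the peaks covered 1.08% of the sequence in replicate 1 and 2.82% in replicate 2. Peaks were also narrower in replicate 1, with a median width of 380 bp against 528 bp. The series-wide list held 7498 peaks, which covered 3.59% of the nuclear sequence with a median width of 287 bp.

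The first comparison asked whether the peaks lay at the same places in both libraries. Most of the smaller list recurred in the larger one: 1250 of 1812 nuclear peaks of replicate 1, or 69.0% (95% exact interval 66.8 to 71.1), overlapped a peak of replicate 2 by at least 1 bp. In the other direction, 1042 of the 3332 peaks of replicate 2 overlapped one of replicate 1, or 31.3% (29.7 to 32.9). When the peaks were moved together to random positions along their chromosomes, the mean overlap was 4.57% for replicate 1 and 2.36% for replicate 2, so the observed shares were 15.1 and 13.2 times higher. A one-sided permutation test with 100000 such shifts gave p = 1e-05 in each direction, the smallest value that this number of shifts can give. The shifts compare with random positions only. The caller's use of the input libraries is not given, so signal that both libraries share without COH-3 binding would recur as well. Together the lists covered 3102 kb, of which 804 kb (25.9%) was covered in both. All intervals on peaks given here cover counting error only, and neighbouring peaks are not independent replicates.

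Higher-scoring peaks recurred more often than lower-scoring ones. In the highest quartile of the caller's score, 89.2% of replicate 1 peaks (95% exact interval 85.95 to 91.9) and 68.3% of replicate 2 peaks (65.0 to 71.5) overlapped the other library. In the lowest quartile the shares were 53.2% (48.5 to 57.9) and 13.3% (11.1 to 15.8). Peaks in the highest quartile were also wider, with medians of 806 bp in replicate 1 and 1433 bp in replicate 2, against 223 bp and 356 bp in the lowest quartile, and a wider peak has more room to overlap another. When at least 50% of the peak had to be covered, the share in the highest quartile of replicate 2 was 37.5%.

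**Figure D1:**
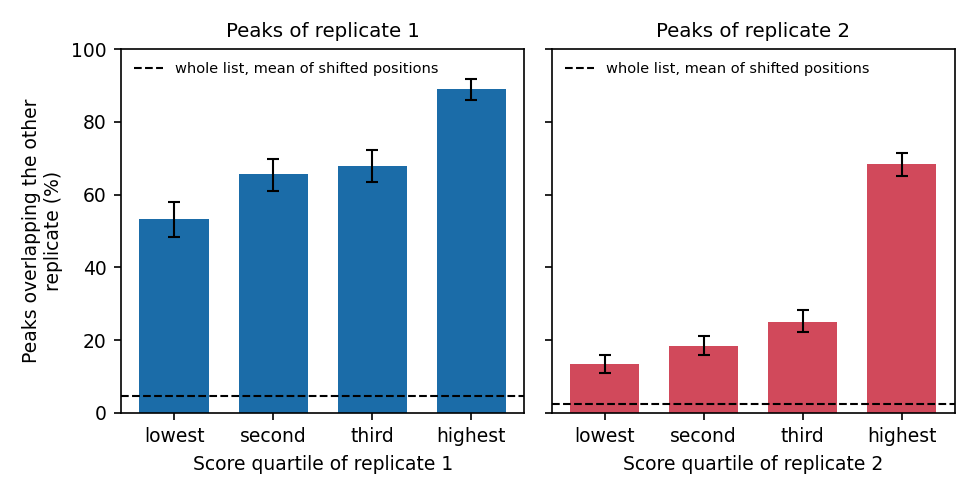
Share of peaks (percent, vertical axis) of each ChIP replicate that overlap a peak of the other replicate, by quartile of the caller's score (horizontal axis). Bars are shares with 95% exact binomial intervals and the dashed line is the mean share of the whole list at shifted positions, 4.57% for replicate 1 and 2.36% for replicate 2. The share is highest in the top quartile, at 89.2% and 68.3%.

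The series-wide list contained nearly every replicate peak. It overlapped 96.6% of the nuclear peaks of replicate 1 (95% exact interval 95.7 to 97.4) and 97.1% of those of replicate 2 (96.5 to 97.6). Of its 7495 nuclear peaks, 1041 (13.9%) overlapped both replicates, 493 (6.58%) only replicate 1 and 2507 (33.4%) only replicate 2. The remaining 3454 (46.1%) overlapped neither. Peaks found in both replicates had a median score of 29.96 and a median width of 858 bp, against 4.40 and 207 bp for those found in neither. The sources used here do not say how the series-wide list was built from the libraries, so its overlap with them is not independent evidence.

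The strongest sites lay on 5 of the 6 nuclear chromosomes. Among the series-wide peaks that overlapped both replicates, the 10 with the highest authors' score comprised 3 on X, 3 on V, 2 on IV, 1 on I and 1 on II, and none on III. These were also the 10 highest-scoring nuclear peaks of the series-wide list as a whole. Coordinates are given on WormBase WS220, equivalent to ce10. The first was a 1728 bp peak on chromosome X from 1503411 to 1505138, with a score of 186.41. The next, with a score of 181.77, spanned 4658 bp on chromosome V from 723583 to 728240. The third was the widest of the 10, at 10911 bp, and ran on chromosome X from 16929343 to 16940253 with a score of 180.97. It overlapped 4 separate peaks in replicate 1 and 2 in replicate 2. The fourth lay on chromosome V from 13907121 to 13909769 with a score of 172.8, and the fifth on chromosome II from 2378315 to 2379107 with a score of 171.57. The fifth was also the highest-scoring peak of replicate 1, with a score of 3171.18. The sixth, with a score of 170.57, was on chromosome IV from 11912894 to 11916252. The seventh, with a score of 168.59, was on chromosome I from 7656513 to 7659324. The others were on chromosome X from 11093658 to 11094597 with a score of 166.04, on chromosome V from 9545079 to 9547480 with a score of 159.9, and on chromosome IV from 11399732 to 11401897 with a score of 154.86. In the replicates' own lists the top peak at these sites reached the score value of 3100, at which 31 peaks of replicate 1 and 118 of replicate 2 were tied, or exceeded it at 8 of the 10 sites in replicate 1 and 9 of the 10 in replicate 2. Whether these sites lie in genes was not analysed here, because the gene table at hand is on another genome build.

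The next comparison set the X chromosome against the autosomes, since X is largely silent during much of germline meiosis in this animal. Replicate 2 had far fewer peaks on X than its length would give, and replicate 1 did not. In replicate 2, X carried 14.8 peaks per Mb and the autosomes 37.2, a ratio of 0.398. This is a log2 ratio of -1.33 (95% exact interval -1.52 to -1.15; exact binomial test, two-sided, adjusted p = 1.71e-59). In replicate 1, X carried 16.8 peaks per Mb and the autosomes 18.3, a log2 ratio of -0.12 (-0.31 to 0.06; exact binomial test, adjusted p = 0.175). X held 298 of 1812 nuclear peaks (16.45%) in replicate 1 and 262 of 3332 (7.86%) in replicate 2, and this difference between the libraries was larger than counting error (Fisher's exact test, two-sided, p = 3.79e-20). Over both libraries X carried 15.8 ± 1.44 peaks per Mb and the autosomes 27.8 ± 13.3 (SD, n = 2). A lower density on X was therefore not found in both replicates, as a call required.

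X was also below the autosomes in the lists that combine the libraries. In the series-wide list X carried 38.7 peaks per Mb against 82.5 on the autosomes, a log2 ratio of -1.09 (95% exact interval -1.21 to -0.98; exact binomial test, two-sided, p = 4.11e-97). In the 1021 regions marked in both replicates the log2 ratio was -0.62 (-0.90 to -0.35; exact binomial test, two-sided, p = 2.27e-06), a value between those of the replicates. These regions need a peak in both libraries, so their number on X is limited by the 262 X peaks of replicate 2. The series-wide list is not independent of the replicates either, and 2507 of its peaks overlapped only replicate 2 against 493 only replicate 1. Its share of peaks on X was 6.46% in the lowest score quartile and 12.2% in the highest, while X makes up 17.7% of the length. X peaks of replicate 1 recurred less often than its autosomal peaks: 144 of 298 (48.3%) overlapped replicate 2, against 1106 of 1514 (73.1%; Fisher's exact test, two-sided, p = 3.71e-16). In replicate 2 the order was the opposite, with 125 of 262 X peaks (47.7%) and 917 of 3070 autosomal peaks (29.9%) found in replicate 1 (Fisher's exact test, two-sided, p = 8.81e-09). These shares depend on how many peaks the other list holds on each chromosome. For replicate 1, shifted positions gave 2.17% on X and 5.04% on the autosomes, so the observed overlap was 22.2 times that at shifted positions on X and 14.5 times on the autosomes. For replicate 2 the corresponding ratios were 20.0 and 12.7. Whether these ratios differ between X and the autosomes was not tested.

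**Figure D2:**
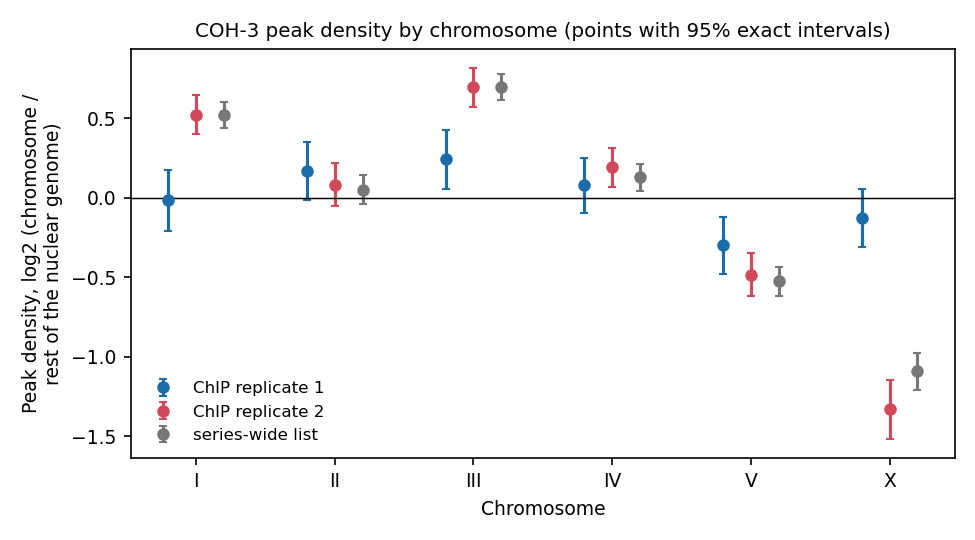
Peak density of each nuclear chromosome (horizontal axis) relative to the rest of the nuclear genome, on a log2 scale (vertical axis), for ChIP replicate 1, ChIP replicate 2 and the series-wide list. Points are log2 ratios and bars are 95% exact binomial intervals. On X replicate 2 is at -1.33 and replicate 1 at -0.12, while III is above 0 and V below 0 in every list.

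Among single chromosomes, III had more and V fewer peaks for their length in both libraries; for V this held for peak number and not for covered bases in replicate 1. Chromosome III carried 20.9 peaks per Mb in replicate 1 and 49.6 in replicate 2, log2 ratios to the rest of the genome of 0.25 (95% exact interval 0.06 to 0.43) and 0.70 (0.57 to 0.82). Adjusted over the 12 exact binomial tests of 6 chromosomes in both replicates, these gave p = 0.0162 and p = 4.86e-26. Chromosome V carried 15.3 and 25.3 peaks per Mb, log2 ratios of -0.30 (-0.48 to -0.12) and -0.48 (-0.62 to -0.35), with adjusted exact binomial p = 0.00171 and p = 8.45e-13. By covered bases, which were not tested, the log2 ratios were 0.18 and 0.69 on III and -0.012 and -0.33 on V in replicates 1 and 2. Chromosome I was enriched in replicate 2 alone, at a log2 ratio of 0.52 (adjusted exact binomial p = 1.56e-15) against -0.01 in replicate 1 (p = 0.895). Chromosome IV passed the threshold in replicate 2 only against a rest that includes the sparsely marked X, at 0.19 (adjusted exact binomial p = 0.00517); against the other autosomes it was at -0.0072 (adjusted exact binomial p = 0.93). In replicate 1 it was at 0.08 against the whole rest (adjusted exact binomial p = 0.385). Chromosome II was at 0.17 and 0.08 and passed in neither library (adjusted exact binomial p = 0.0936 and p = 0.274). Against the other autosomes alone, III remained above in both replicates, at 0.23 and 0.52 (adjusted exact binomial p = 0.0347 and p = 7.24e-15). V remained below, at -0.34 and -0.71 (adjusted exact binomial p = 0.000342 and p = 6.20e-26). This comparison was added after the data were examined, and for III the other autosomes include V. In replicate 1, III at 20.9 peaks per Mb was little above II at 20.0, with IV at 18.9 and I at 17.9. Whether III stands out without V was not tested. Along III, bins of 1 Mb held from 6 to 31 peaks in replicate 1. The exact binomial tests make no allowance for such unevenness, so the excess of III in replicate 1 is less certain than p = 0.0162 reads.

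Within chromosomes, the peaks were set against the division of autosomes into a gene-dense centre and repeat-rich, more recombining arms, taken here as the central 33.3% of the length and the rest. Replicate 1 had more autosomal peaks in the centre, with 20.9 per Mb against 17.1 in the outer parts, a log2 ratio of 0.29 (95% exact interval 0.14 to 0.44; exact binomial test, two-sided, adjusted p = 0.000372). Replicate 2 had 36.9 per Mb in the centre and 37.3 outside, a log2 ratio of -0.016 (-0.13 to 0.09; adjusted exact binomial p = 0.789). The share of autosomal peaks in the centre was 37.9% in replicate 1 and 33.1% in replicate 2, a difference beyond counting error (Fisher's exact test, two-sided, p = 0.00137). By chromosome, the share in replicate 1 ran from 31.7% on IV to 45% on V, so it was not raised on every autosome. In replicate 2 it ran from 28.2% on V to 37.3% on III. These shares of single chromosomes were not tested. With the central 50% of the length taken as the centre, both libraries passed, replicate 2 only narrowly. The log2 ratios were 0.48 (0.33 to 0.63) and 0.11 (0.004 to 0.21; adjusted exact binomial p = 2.84e-10 and p = 0.0414). By covered bases, which were not tested, the log2 ratios for the central 33.3% were 0.44 in replicate 1 and 0.079 in replicate 2.

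On X the middle was sparsely marked in replicate 2. Its centre carried 9.14 peaks per Mb and its outer parts 17.6, a log2 ratio of -0.95 (95% exact interval -1.41 to -0.51; exact binomial test, two-sided, adjusted p = 1.46e-05). In replicate 1 the values were 16.42 and 17.02 per Mb, a log2 ratio of -0.05 (-0.42 to 0.31; adjusted exact binomial p = 0.806). The share of X peaks in the centre differed between the libraries, at 32.6% and 20.6% (Fisher's exact test, two-sided, p = 0.00162).

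**Figure D3:**
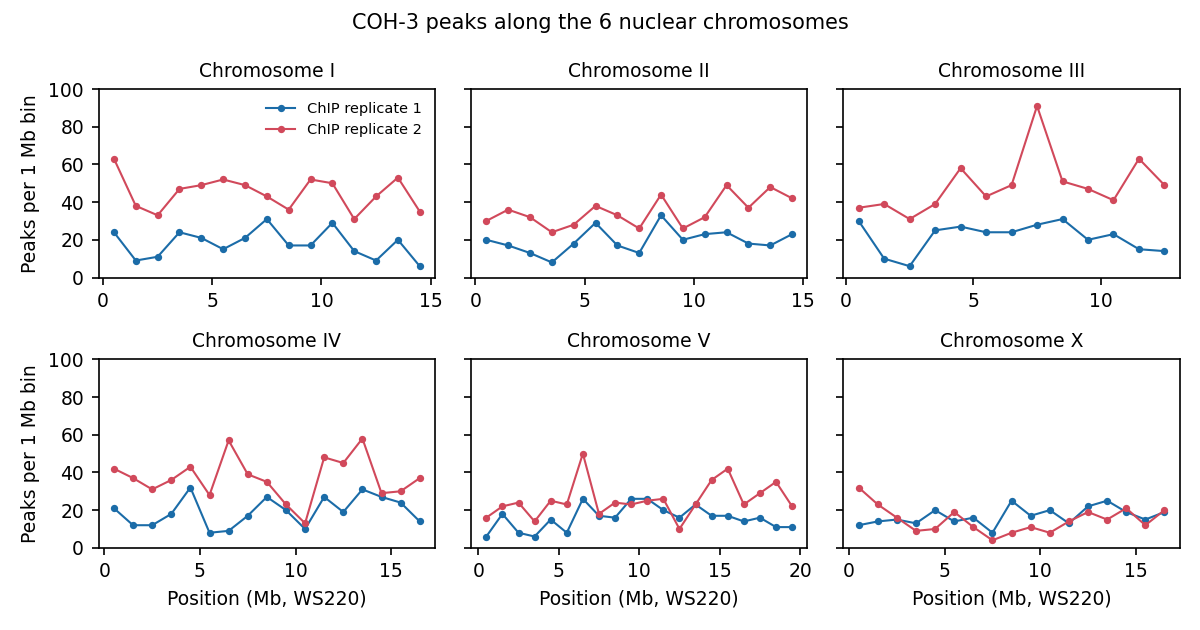
Number of COH-3 peaks per 1 Mb bin (vertical axis) along each of the 6 nuclear chromosomes (horizontal axis, Mb on WS220) in ChIP replicates 1 and 2; the incomplete last bin of each chromosome is left out. Replicate 2 peaks at 91 in the bin of chromosome III that starts at 7000001, where replicate 1 has 28, while on X the bins of both replicates lie between 4 and 32.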

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

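The overlap of the replicates exceeded that at shifted positions under each alternative, with shares of 56.2% to 73.1% for replicate 1 and 20.0% to 44.6% for replicate 2; the lowest share came from equal numbers of peaks in replicate 1 and from requiring 50% of the peak to be covered in replicate 2. That requirement lowered the share in the highest score quartile to 84.5% in replicate 1 and 37.5% in replicate 2. It also changed the share of series-wide peaks found in both replicates to 9.03% and in neither to 48.5%, and the shares of replicate peaks found in the series-wide list to 94.2% and 92.6%; with the stricter threshold the last of these was 96.0%. By construction the stricter threshold gave a mean of 1286 peaks per list. The mean log2 ratio of X over autosomes over the replicates, -0.73, passed no joint test in the replicates' lists, and passed with the series-wide list (-1.09) and in the shared regions (-0.62). With one replicate alone it ranged from -1.33 (replicate 2, called) to -0.12 (replicate 1, not called), so the joint call fails on replicate 1. In replicate 1 the sign itself was open, at 0.16 in its better-scoring 50% (exact binomial adjusted p = 0.192) and 0.01 after merging peaks closer than 500 bp. The autosomal centre ratio, 0.14 in the mean, ranged from -0.016 (replicate 2 alone) to 0.29 (replicate 1 alone). It was called in replicate 1 alone, in the series-wide list (0.29) and with the central 50% (0.29), where replicate 2 passed only narrowly. On X the mean was -0.50, from -0.05 in replicate 1 and -0.95 in replicate 2. The cause was not tested. The number of chromosomes called was 2 in both replicates together and ranged from 2 (replicate 1 alone) to 5 (replicate 2 alone). With X left out and each autosome set against the others, it was 2 in both replicates together and 3 in replicate 2. The stricter threshold, equal numbers of peaks and merging were not applied to the calls of single chromosomes. Measured by covered bases, chromosome V was at -0.012 in replicate 1 and -0.33 in replicate 2, with a mean of -0.17 against -0.39 by peak number, and the mean of chromosome II was -0.03 against 0.13. Leaving out peaks near chromosome ends or wider than 5 kb, an alternative chosen after the data were examined, changed no call on the replicate overlap, X, the autosomal centre or the single chromosomes. No paired analysis was possible because the input libraries that share the replicate numbers have no values here. The alternatives listed beforehand for gene starts, feature classes, gene lists and GC content were not run, as no annotation of WS220 was at hand. Depth is unknown, so how far the shorter list of replicate 1 reflects fewer reads was not assessed.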

Other observations

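The tests of the X difference and of the unmatched series-wide peaks were chosen after those values were seen. The spacing tests were set before, except that the merged distances, first to be judged over both replicates jointly, were judged for each replicate only after they were seen. Along the autosomes the peak numbers of both libraries varied together. Peaks found in both libraries count in both numbers, so this relation is not separate from the overlap given above. Over 80 bins of 1 Mb, Pearson's r was 0.43 (permutation p = 0.00014, adjusted 0.00056) and Spearman's rho 0.43 (permutation p = 0.00014, adjusted 0.00056), and r stayed at 0.42 without the 2 bins farthest from the median of replicate 1. Over the 17 bins of X, r was -0.07 (permutation p = 0.787, adjusted 0.787) and rho -0.11 (permutation p = 0.664, adjusted 0.664); without 2 bins r was 0.07. For peaks found in one library alone, r was -0.11 on the autosomes (permutation p = 0.343, adjusted 0.457) and -0.45 on X (permutation p = 0.0688, adjusted 0.138), and the latter was -0.17 without 2 bins; rho was -0.07 (adjusted 0.664) and -0.48 (adjusted 0.111). These were 4 relations across bins, which are not independent replicates.

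All 3 lists had a peak within 2 bases of the left end of each of the 6 nuclear chromosomes. The widest nuclear peak of replicate 1 spanned 11149 bp on chromosome I from 15060205 to 15071353, close to the right end, where the array of large ribosomal RNA genes lies in this species. A peak of 11172 bp lay at the same place in replicate 2, from 15060194 to 15071365. The widest peak of replicate 2 spanned 15306 bp on chromosome I from 10204025 to 10219330. Peaks covered 13374 bp of mitochondrial DNA in replicate 1 and 13042 bp in the series-wide list, and replicate 2 listed no mitochondrial peak.

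The libraries differed in the share of peaks on X, 16.45% against 7.86%. The length of the list alone does not account for this. The 1812 top-scoring peaks of replicate 2 still had a log2 ratio of X over autosomes of -1.36 (95% exact interval -1.62 to -1.11), below the interval of replicate 1. Cutting that list does not show what a shallower or less enriched library would give, so depth and enrichment remain open. The lower-scoring 50% of replicate 1 held 13.6% X peaks and its upper 50% held 19.3%, a difference of -5.74 percentage points (Fisher's exact test, two-sided, p = 0.0012). Over the whole list, X peaks were thus not concentrated among the weaker peaks. The split mixes peaks found in both libraries with peaks of replicate 1 alone, whose median score was lower (87 against 160.66). Weak background peaks among the latter are therefore not excluded. A difference in the animals or in library preparation also stays open, since the labels of both libraries describe animals and protocol alike and each stands alone. The caller's threshold and use of input for each replicate are not given, so they stay open too. The deposited peak lists of the libraries are named by different schemes, which states no batch or animals. Among replicate 1 peaks not found in replicate 2, 27.4% were on X, against 11.5% of those found in it. X makes up 17.7% of the length. Of the replicate 2 peaks not found in replicate 1, 5.98% were on X. No biological explanation was tested, because the design names none between the replicates.

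Of the series-wide nuclear peaks, 46.1% had no counterpart in a replicate. These had lower scores and were narrower than the rest, so both weaker sites under the replicates' thresholds and a lower chance of overlap for narrow peaks are candidate explanations. The share without a counterpart was higher in the lower-scoring 50% than in the higher-scoring 50% in 4 of 4 quartiles of width. The gap was widest in the third, at 53.9% against 10.2%, and small in the narrowest, at 86.3% against 81.3%. It was also higher in the narrower 50% than in the wider 50% in 4 of 4 quartiles of score, for example 54.96% against 11.6% in the third. Score and width stay linked within quartiles, so both explanations remain open. The caller named for the series-wide list also differs from that of the replicates. How far the caller or its setting accounts for the unmatched peaks was not tested.

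Neighbouring peaks lay closer together than the regional density of peaks gives. The median distance between neighbouring midpoints was 22959 bp in replicate 1 and 12907 bp in replicate 2, against means of 27627 and 15877 bp when midpoints were redrawn within their own windows of 100 kb (1000 redraws, one-sided permutation p = 0.000999 in each, the smallest they can give). Splitting of one enriched region by the caller is a possible explanation for part of this. Peaks closer than 500 bp were therefore merged, and the midpoints of the merged peaks were redrawn in the same way, without merging the redraws. In replicate 2 the median distance after merging, 19852 bp, still lay below the middle 95% of redraws (20675 to 22181 bp), so splitting at that distance does not account for all of the closeness there. In replicate 1 it was 39650 bp and lay within them (38551 to 42207 bp). Merging removes short distances whether they come from splitting or from separate sites, so in replicate 1 the explanations cannot be told apart.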
